A study of Mus musculus with 8 samples.

How the data were processed

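Single-cell RNA sequencing of dissociated mouse pituitaries was reanalysed from 8 libraries. Mutant mice carried Cre recombinase under a growth hormone promoter and a floxed first exon of the leptin receptor gene, Lepr. Controls were littermates without Cre. Each sex and genotype had 2 libraries, and each library was made from a pool of several pituitaries. The deposited matrices hold raw UMI counts per gene and barcode. Per the submitters' processing notes, Cell Ranger (7.1 and 3.1.0 are both named), STAR and Seurat were used on builds mm10 and GRCm38, with no role given for each. Every deposited matrix lists 28810 genes and exactly 6000 barcodes per library, 48000 in all, and how that number was set is not stated. The gene list ends with 117 identifiers of bacteriophage P1 genes, and it holds a custom entry named Prop1L. Of the 28693 Ensembl identifiers, 28339 were found in the GENCODE M21 annotation of GRCm38, 27194 of them under the same gene name. The annotation release used by the authors is not stated. Coordinates are 1-based positions from GENCODE M21. Because 58 symbols are used by more than 1 gene of the files, genes were joined by identifier.

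The libraries held between 13414345 and 27056510 UMIs. Barcodes were kept with at least 500 genes and at most 20% mitochondrial UMIs. In each library the 5% of barcodes with the highest Scrublet doublet score were then removed, since Scrublet's own threshold called between 0.0% and 0.62% of barcodes. This left 13935 barcodes. Counts were log-normalised in scanpy 1.11.5, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 34 clusters, without batch integration (leidenalg 0.10.2, scikit-learn 1.9.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3; random seed 1).

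Clusters were named from 15 fixed lists of cell type markers. A cluster took the class of highest mean marker fold over the median cluster. It had to have at least 3 markers at 2-fold or more and in at least 3% of its cells, a score at least 0.5 above the next class, and no other class with more markers among its 10 leading genes. Clusters whose profile lay within a distance of 0.15 of free RNA stayed unnamed, free RNA being the 2000 barcodes of fewest UMIs per library. The marker lists were fixed beforehand, but these numeric thresholds and the rule on free RNA were written after the files were seen. Of the 34 clusters, 6 stayed unnamed, with 29.4% of kept barcodes. The other clusters gave 11 classes, and 7 of these had at least 20 cells in every library and were tested. Gh, Ghrhr, Pappa2, Wnt10a, Dlk1 and Pou1f1 named the somatotropes, so their level in that class is partly set by the naming.

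UMI counts were summed per library and class. Genes were tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr, 1 mean per group, and the robust quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. All 8 libraries shared the estimate of spread. The contrasts were mutant against control in females, in males and over both sexes, the difference between these effects (genotype by sex), and female against male controls. Fold changes are log2 values with a standard error (SE), and levels are CPM, counts scaled to library size by edgeR, with the standard deviation (SD) of 2 libraries. Values of Hspa1a, Hba-a1, Cxcl10 and Rsad2 given per library, and those compared with free RNA, are scaled to the UMI total of the class, without TMM. Plots show CPM on a log axis with nothing added. The levels of gene lists per library, and the rule on which side of the controls a library lies, add 1 CPM before taking logs. The most that free RNA could bring to a class was bounded by taking all its Prl (somatotropes) or Gh (gonadotropes) as free RNA, a bound added after the data were seen. Where a library had no UMI of a gene, the floor is 3 counts of its class total. Intervals are exact Clopper-Pearson at 95%. Intervals and floors cover counting error only.

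Gene lists, 21 in number besides the cell type markers, were fixed by function. They were tested with camera (limma 3.58.1, inter-gene correlation preset at 0.01, two-sided). Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance without comparing them with other genes, were alternatives. In somatotropes 24 lists had enough measured members for the test. Shares of kept barcodes were compared by exact permutation of the 4 libraries of a sex over 6 splits, two-sided, for which 0.333 is the smallest p possible. Female and male fold changes were related by Spearman and Pearson correlation across genes, which are not independent replicates.

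The samples, contrasts, gene lists, markers, filters and all alternatives but those named below as chosen later were fixed before the data were examined. So was the rule for named genes. In somatotropes it takes the 10 risen and 10 fallen genes of smallest p, in each sex, among those past the threshold with both mutant libraries on the same side of both controls. It takes 5 per direction for both sexes together, the interaction and the control sex difference, and 3 per direction, class and sex elsewhere. Gene models named Gm or Rik were left out. Up to 4 members of smallest p were named per list, and Lepr, Gh, Ghrhr, Ghsr, Pou1f1, Prl, Pomc, Cga, Tshb, Lhb, Fshb, Msi1, Msi2, Socs3, Stat3, Xist and Ddx3y were always considered. Genes outside the rule are marked as chosen after their values were seen. Some genes that the rule takes are not reported here.

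The pipeline was tested on simulated somatotrope counts, drawn for every gene from a negative binomial model. Each gene's mean level and spread were taken from all 8 libraries together and were the same for both sexes. The means of 200 genes per comparison were changed before drawing. Of genes changed 4-fold, 81% were recovered in females and 88% in males. Of genes changed 2-fold, 24% and 42% were recovered, or 52.9% and 75% at a mean of 50 CPM or more. False calls were 3.6% of calls in females and 7% in males. A raised list was found in both sexes, with 0 other lists called. The genes were drawn independently of each other, so this cannot show how the list tests behave where genes vary together.

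Alternatives tried were the DESeq2 1.42.0 Wald test, DESeq2 size factors or library totals in place of TMM, no filter on low counts, and only the 4 libraries compared. Others were a block for the replicate number in the labels, leaving out each library, at least 200 genes or at most 10% mitochondrial UMIs per barcode, no removal by Scrublet score, and Leiden resolution 0.5. Genes 5 times or more higher in another class were left out, equal numbers of cells were drawn (74 somatotropes per library), and all kept cells were summed. Shares were also taken of endocrine cells and tested as cell counts in edgeR. Chosen after seeing the data were cells with at least 1500 genes, the high-UMI somatotrope cluster alone, removal of each library's trend with transcript length (for genes, and for lists in somatotropes), DESeq2 size factors for list tests, and shares of named cells. Corticotropes, lymphocytes, pituicytes and stromal cells had too few cells in some library and were not tested for gene changes. Reads were not used here, so splicing and the deleted exon were not examined. Figures were drawn with matplotlib 3.10.9.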

Results

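Messenger RNA of single pituitary cells was counted in 8 libraries, 2 for each of 4 groups: control females, control males, mutant females and mutant males. The mutants expressed Cre from a growth hormone promoter, which acts in somatotropes, the growth hormone cells of the anterior pituitary, and carried a floxed first exon of Lepr, the leptin receptor. In the order control female, control male, mutant female, mutant male, replicate 1 before replicate 2, the libraries held 27056510, 21240967, 16790148, 17198496, 14541580, 23125387, 13414345 and 15399171 UMIs. After filtering, 1937, 1272, 1838, 1275, 993, 4778, 873 and 969 barcodes were kept. Of these, 205, 82, 289, 185, 92, 74, 108 and 98 were named somatotropes, with 1491674, 825250, 2035492, 1384036, 768865, 652091, 893849 and 932912 UMIs. The 3-count floor per library was therefore between 1.47 and 4.6 CPM.

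The labelled sexes matched the data. Xist, which coats the inactive X chromosome, had 10354 to 22406 UMIs in each female library and 1 to 5 in each male library. Ddx3y, a Y-linked RNA helicase, had 0 UMIs in each female library and 938 to 1384 in each male library. The genotypes were matched by P1_gp003, a bacteriophage P1 identifier in the gene list, whose transcript was counted in all 4 mutant libraries and in 0 of the 4 controls. Mutant female replicate 2 stood apart from the others. Hemoglobin transcripts made up 3.539% of UMIs in its 2000 barcodes of fewest UMIs, against 0.165% to 0.627% in the other libraries. A cluster with the profile of free RNA held 2836 barcodes, 2788 of them from that library.

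Lepr itself was too scarce in somatotropes to be compared. A Lepr UMI was found in 2 of 761 control somatotropes (0.263%, 95% interval 0.0318 to 0.946%) and in 0 of 372 mutant somatotropes, which allows up to 0.987% of cells with a UMI. In endothelial cells, where P1_gp003 was found in 0 of 520 mutant cells, Lepr UMIs were found in 12.7% of 826 control and 11.3% of 520 mutant cells. The tags lie near the 3' end of transcripts, so loss of the first exon could not be seen in them. Ghsr, the ghrelin receptor, had 0 to 3 UMIs per library in somatotropes and was not tested.

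Somatotropes of mutant and control males were compared to ask how the growth hormone cells differ where Cre was expressed. The levels of 5 named genes show the size of the changes. Slc2a1, the glucose transporter GLUT1 (chromosome 4, 119108711 to 119137983, ENSMUSG00000028645), rose 8.02-fold, from 19.52 ± 8.23 to 163.2 ± 49.9 CPM (SD, n = 2 pools per group). Serpinh1, the collagen chaperone HSP47 (chromosome 7, 99345376 to 99353239, ENSMUSG00000070436), rose 7.34-fold, from 23.68 ± 12.8 to 165.9 ± 13.2 CPM. Pabpc1, the cytoplasmic poly(A)-binding protein (chromosome 15, 36595661 to 36609668, ENSMUSG00000022283), rose 3.31-fold, from 150.7 ± 7.48 to 499.7 ± 56.0 CPM. Cacna1d, an L-type calcium channel subunit (chromosome 14, 30039939 to 30491455, ENSMUSG00000015968), rose 2.63-fold, from 89.93 ± 12.8 to 235.9 ± 11.2 CPM. Bdnf, a neurotrophin (chromosome 2, 109674700 to 109727007, ENSMUSG00000048482), fell 3.18-fold, from 45.07 ± 5.15 to 13.82 ± 4.33 CPM.

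Of 8247 genes tested in male somatotropes, 217 were higher and 52 lower in mutants at an adjusted p under 0.05 in edgeR's quasi-likelihood test. The smallest adjusted p values belonged to Pabpc1 (log2 1.73, SE 0.18, adjusted p = 3.55e-06), Slc2a1 (3.00, SE 0.29, 9.75e-06) and Serpinh1 (2.88, SE 0.29, 1.11e-05). The other risen genes of smallest p were Mast4 (1.68), mt-Atp8 (2.25), Snrnp70 (1.54), Tmem243 (1.90), Baiap2 (1.76), Cacna1d (1.40) and Ralgds (2.08), with adjusted p from 2.39e-05 to 9.02e-05. Baiap2 stood at -0.38 when only cells with at least 1500 genes were summed, a setting with 23 and 12 somatotropes in the mutant male pools. The 10 fallen genes were Morn2 (-1.59), Cyb5a (-1.10), Bdnf (-1.67), Htatsf1 (-0.89), Atraid (-0.94), Polr2j (-1.25), Ndufa4 (-0.85), Ndufb3 (-0.92), Cnpy2 (-0.88) and Nudt2 (-1.90), with adjusted p from 0.000345 to 0.0126. The DESeq2 Wald test called 82 genes, 80 higher and 2 lower in mutants, so few of the fallen genes passed it. Of the 82, 74 were also called by edgeR, and edgeR called 90 genes with equal numbers of cells per library. Calls fell to 116 and 136 without control male replicates 1 and 2, and to 175 and 95 without mutant male replicates 1 and 2.

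**Figure D1:**
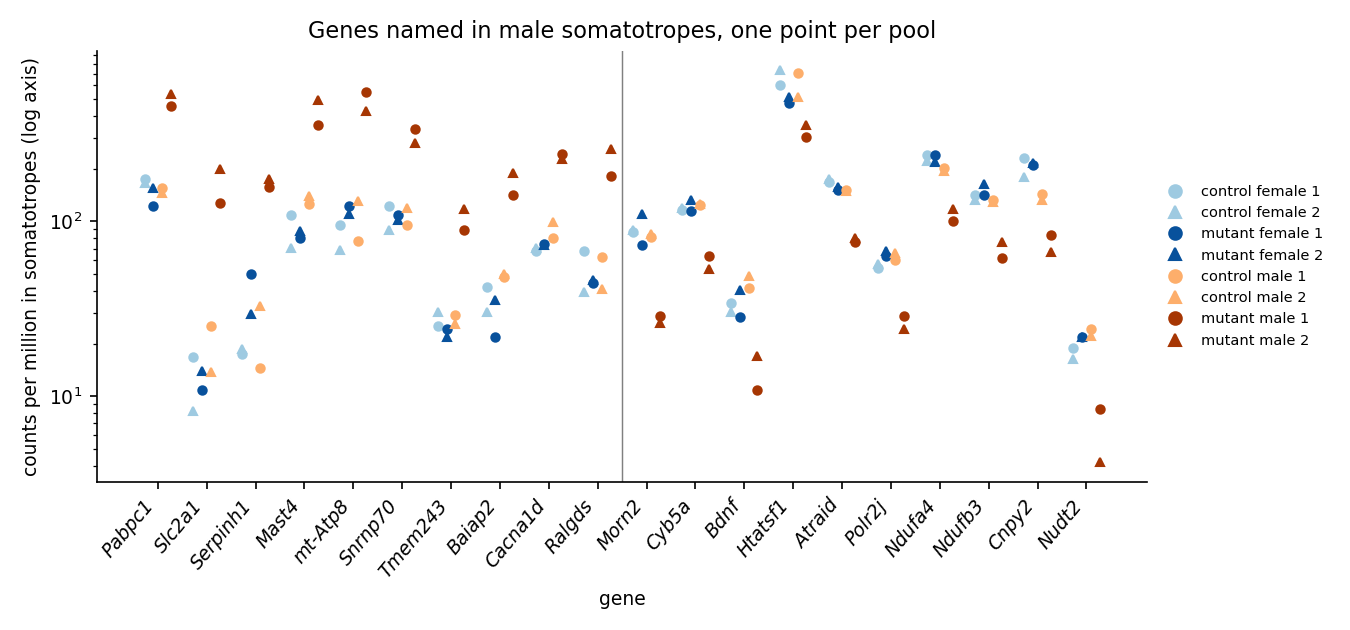
Levels of 20 named genes in somatotropes, with 1 point per pool and CPM on a log axis. The 10 genes left of the grey line rose in mutant males and the 10 to its right fell, as for Slc2a1 at a mean of 19.52 CPM in control males and 163.2 CPM in mutant males.

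Growth hormone itself and its regulators did not pass the test in males. Gh stood at 312400 ± 1500 CPM in control and 273200 ± 61500 CPM in mutant male somatotropes (log2 -0.19, SE 0.17, adjusted p = 0.605). Ghrhr, the receptor for growth hormone releasing hormone, had a log2 value of -0.32 (SE 0.21, adjusted p = 0.47), and Pou1f1, the lineage transcription factor, one of -0.18 (SE 0.18). These 3 genes helped to name the class. In the list of growth hormone axis regulators, 0 of 15 measured genes rose or fell, and 1 rose when adjusted over the list alone (Neurod4, 0.93, SE 0.27; median -0.12, camera adjusted p = 0.772). Of the hormone genes of other endocrine cells, Prl (-0.04), Pomc (-0.91), Cga (-0.61), Tshb (-2.15), Lhb (0.56) and Fshb (0.50) did not pass the test. Pcsk2, a prohormone convertase, rose (2.19, SE 0.34, adjusted p = 0.000323). It was the only 1 of 8 measured members of that list to do so, also when adjusted over the list alone, with a list median of -0.14 but an upward camera direction (adjusted p = 0.881). In cells with at least 1500 genes, 23 and 12 in the mutant male pools, that list was called downward (0.0141).

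Some genes of leptin signalling passed the test in male somatotropes, where 217 of all 8247 genes rose and 52 fell. In the leptin receptor and JAK-STAT list, 3 of 28 measured genes rose and 0 fell (Ptpn1, a phosphatase acting on JAK2, 0.86; Jak2, 1.24; Jak1, 0.78), and 4 rose when adjusted over the list alone (median 0.15, camera adjusted p = 0.344). When only cells with at least 1500 genes were summed, 23 and 12 in the mutant male pools, this list was called downward (adjusted p = 0.00398). Socs3, the feedback inhibitor of leptin signalling, had a log2 value of -1.55 (SE 0.75, adjusted p = 0.407) and Stat3 of 0.52 (SE 0.24, 0.289). The Musashi RNA-binding proteins Msi1 (-0.11, SE 0.42) and Msi2 (0.28, SE 0.2) did not pass either.

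Of 22 measured genes of cholesterol and fatty acid synthesis, 6 rose in male mutant somatotropes and 0 fell, 12 rose when adjusted over the list alone, and 21 had positive values (median 0.83, camera adjusted p = 1.78e-11; adjusted p = 0.0645 with an estimated correlation). Hmgcs1 (1.80, SE 0.26), Msmo1 (1.52, SE 0.26), Insig1 (1.25, SE 0.24) and Fdft1 (1.23, SE 0.26) led the list. Of 15 heat shock and chaperone genes, 8 rose and 0 fell, and 10 rose when adjusted over the list alone (median 0.82, camera adjusted p = 1.53e-11; adjusted p = 0.0645 with an estimated correlation). Dnaja1 (2.29-fold, SE 0.17 on the log2 scale), Dnajb4 (1.53, SE 0.23), Bag3 (1.45, SE 0.25) and Hspd1 (0.82, SE 0.19) were its leading members. Of 17 glycolysis genes, 4 rose and 0 fell, also when adjusted over the list alone: Slc2a1, Hk2 (2.15, SE 0.31), Eno2 (2.29-fold, SE 0.29 on the log2 scale) and Tpi1 (0.72, SE 0.18), with a list median of 0.42 (camera adjusted p = 2.29e-06; adjusted p = 0.138 with an estimated correlation).

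Of 71 nuclear-encoded oxidative phosphorylation genes, 0 rose and 5 fell, 8 fell when adjusted over the list alone, and 13 had positive values (median -0.23, camera adjusted p = 5.93e-06; adjusted p = 0.0645 with an estimated correlation). Ndufa4, Ndufb3 and Ndufb7 (-0.85, SE 0.22) were among them. The fall of this list is not told apart from transcript length: 28 of its genes have transcripts of 0.6 to 1 kb, and genes of that length outside the list had a median of -0.35. With each library's trend with length removed, the list had a median of -0.07, 3 genes fell, 5 fell adjusted over the list alone, and the call was lost (adjusted p = 0.133). Ndufa4, Ndufb3 and Cnpy2 then kept their direction but did not pass. Of 13 mitochondrially encoded transcripts, 2 rose and 0 fell, also when adjusted over the list alone: mt-Atp8, a subunit of ATP synthase, and mt-Nd4l (0.98, SE 0.19), with 11 positive values (median 0.19, camera adjusted p = 0.00795; adjusted p = 0.936 with an estimated correlation). Glucocorticoid response genes included 2 of 13 that rose, Sgk1 (1.62, SE 0.42) and Ddit4 (0.88, SE 0.25), and 0 that fell; adjusted over the list alone 4 rose and 1 fell (median 0.68, camera adjusted p = 0.00708; adjusted p = 0.813 with an estimated correlation). In cells with at least 1500 genes, 23 and 12 in the mutant male pools, the glucocorticoid list turned downward (adjusted p = 0.153).

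The remaining lists were not called by camera in male somatotropes. Ribosomal protein genes had 8 of 81 members that rose (9 adjusted over the list alone), among them Rps29 (1.07), Rps27 (0.87), Rpl38 (0.82) and Rps28 (1.01), while 25 were positive and the median was -0.16 (adjusted p = 0.655). Of 25 immediate early genes Btg1 rose (1.44, SE 0.31; also adjusted over the list alone), with a median of -0.46 (0.637), and of 25 unfolded protein response genes Hspa5 rose (0.83, SE 0.15; also adjusted over the list alone), with a median of -0.09, a mean of 0.07 and an upward direction (0.881). Of 16 interferon response genes 2 rose, Gbp2 (1.88) and Rsad2 (2.01), also when adjusted over the list alone (median 0.12, 0.13), and in cells with at least 1500 genes the list was called downward (0.0194). Of 28 secretory granule genes Snap25 rose (0.78), or 3 adjusted over the list alone (median -0.02, mean 0.11, upward, 0.637). Of 18 ion channel genes Cacna1d rose, also adjusted over the list alone (median 0.13, 0.151). Of 17 clock genes Rorb rose (1.16), or 2 up and 1 down adjusted over the list alone (median 0.30, 0.289).

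Smaller lists in male somatotropes gave the following values. Of 13 MAPK feedback genes Phlda1 rose (2.06, SE 0.5), also adjusted over the list alone (median 0.02, 0.637). Of 9 sex steroid genes Greb1 rose (0.78, SE 0.22), or 2 adjusted over the list alone, with a median of -0.11, a mean of 0.06 and an upward direction (0.68). In Notch and Wnt signalling (5 measured, median 0.31, 0.714) and TGF-beta, activin and BMP signalling (16 measured, median 0.02, mean -0.01, upward, 0.881), 0 genes passed, also adjusted over the list alone. Of 2 cell cycle genes measured, 0 passed over all genes and Stmn1 (-0.47) passed adjusted over the list alone. Among markers of other cell types in male somatotropes, Pcsk2, a melanotrope marker, was the only gene to pass. The medians were -0.21 for 4 lactotrope markers (0.637), 0.50 for 3 gonadotrope markers (0.881), -0.05 for 4 thyrotrope markers (0.933) and -1.20 for 3 erythroid markers (0.489). Too few to test were 1 corticotrope (Pomc), 2 melanotrope (median 0.64), 2 stem cell (1.38), 1 stromal (0.39), 1 macrophage (-0.76), 2 lymphocyte (0.15) and 1 pituicyte marker (-0.06); endothelial, mural and proliferating markers had 0 measured.

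In total, camera called 6 of 24 lists in males, 0 of them with an estimated correlation, and fry called 4. TMM, library totals and DESeq2 size factors gave each called list in male somatotropes the same sign of its median, with a largest median shift over all genes of -0.03.

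The same comparison was made in female somatotropes. The growth hormone gene and its main regulator gave values on either side of 0. Gh stood at 334400 ± 25300 CPM in control and 339400 ± 77900 CPM in mutant females (SD, n = 2 pools per group; log2 0.02, SE 0.17). Ghrhr had 97.1 ± 0.204 CPM in controls and 56.08 ± 6.94 CPM in mutants (-0.79, SE 0.23, adjusted p = 1.0), and it passed only when adjusted over the list alone, 1 of 15 growth hormone axis genes. Pou1f1 (-0.15), Prl (-0.66), Pomc (-0.25), Cga (0.15), Tshb (0.32), Lhb (-0.71), Fshb (-0.72), Msi1 (0.06, SE 0.55), Msi2 (-0.50, SE 0.21), Socs3 (-0.01, SE 0.74) and Stat3 (0.02, SE 0.28) did not pass. Of 8247 genes, edgeR called 0, with 282 at an unadjusted p under 0.05, and DESeq2 called 0, with 73. Without mutant female replicate 2 the count was 14, and without mutant female replicate 1 it was 6. Without either of the mutant male replicates it was 1.

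Gene lists in female somatotropes were called without any single gene passing. Heat shock and chaperone genes were positive in 14 of 15 (median 0.54), with 0 called over all genes and 3 that rose adjusted over the list alone; Hspa8 (0.54, SE 0.16), Dnaja1 (0.54), Hsp90aa1 (0.46) and Dnajb1 (1.29, SE 0.42) had the smallest p (camera adjusted p = 1.65e-08; adjusted p = 0.15 with an estimated correlation). The level of this list lay above control females by 1.09 in mutant female replicate 1 and by 0.27 in replicate 2. Ribosomal protein genes were positive in 69 of 81 (median 0.15), with 0 called either way; Rps29 (0.57), Rps27 (0.53) and Rps28 (0.69) led (camera adjusted p = 1.34e-05; adjusted p = 0.675 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes were positive in 53 of 71 (median 0.10), with 0 called either way (camera adjusted p = 0.00203; adjusted p = 0.15 with an estimated correlation), a call lost with the length trend removed (median 0.05, adjusted p = 0.341). All 3 erythroid markers were positive (median 2.80), with 0 called either way (camera adjusted p = 0.000111; adjusted p = 0.453 with an estimated correlation), and this list turned downward without mutant female replicate 2 (0.314), the library rich in free hemoglobin. Hba-a1 was at 351 CPM in somatotropes of that library and at 12.1 to 95.8 CPM in the others. Camera with an estimated correlation and fry each called 0 of 24 lists in females.

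The other lists had 0 genes called in female somatotropes and were not called by camera. Adjusted over the list alone, 1 mitochondrially encoded transcript rose (mt-Nd4l, 0.71) and 1 lymphocyte marker fell (Cd79b, -2.70). Signs of median, mean and camera differed for sex steroid genes (-0.16, -0.08, upward), gonadotrope markers (median -0.71, upward), MAPK genes (0.02, -0.06, downward), mitochondrially encoded transcripts (-0.03, 0.02, upward), glycolysis (0.05, -0.02, upward) and TGF-beta signalling (-0.00, 0.05, upward). Immediate early genes had a median of 0.27 and a level of -1.39 in mutant female replicate 1 and 0.99 in replicate 2 relative to control females. Without mutant female replicate 2 this list was called downward (adjusted p = 2.82e-38). Without control female replicate 2, gonadotrope markers (0.00104) and mitochondrially encoded transcripts (0.0488) were called downward.

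Over both sexes, a joint test found a small group of genes higher in mutant somatotropes. Amd1, which makes decarboxylated S-adenosylmethionine for polyamine synthesis, rose 2.5-fold (log2 1.32, SE 0.21, adjusted p = 0.00179; n = 4 pools per genotype), from 22.53 and 30.15 CPM in control females and males to 45.62 and 86.9 CPM in mutants. Rps27, a ribosomal protein (0.70, SE 0.11), mt-Nd4l, a complex I subunit (0.85, SE 0.14), Dnajb4, a heat shock co-chaperone (0.93, SE 0.18), and Hspa8, the constitutive HSP70 (0.57, SE 0.11), also rose, with all 4 mutant pools above all 4 controls. Heat shock genes had 5 of 15 that rose and 9 when adjusted over the list alone (camera adjusted p = 6.9e-20; 0.0438 with an estimated correlation), and cholesterol and fatty acid synthesis 2 of 22 and 6 adjusted over the list alone (camera adjusted p = 4.48e-10; 0.0438 with an estimated correlation). Glycolysis (0.00154) and mitochondrially encoded transcripts (0.00818) were also called, with adjusted p = 0.411 and adjusted p = 0.89 with an estimated correlation. EdgeR called 39 genes higher and 3 lower, 42 in all; the 3 lower were Htatsf1 (-0.66), Ppib (-0.89) and Morn2 (-0.77), chosen after their values were seen. In 14 of the 42 all mutant pools lay on 1 side of all controls, which held for 3.0% of genes tested where chance gives 2.9%. With sex as a term in the model the contrast gave 25 calls, and another split of the 8 libraries gave 71. That split also set both mutant male pools against both control male pools. It therefore cannot decide whether chance gave the calls, or whether they hold in both sexes. DESeq2 called 22, of which 17 were shared, and the count was 19, 26, 16 and 77 without control female replicate 2, control male replicate 1, mutant male replicate 2 and mutant female replicate 2.

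Whether the genotype effect differed between the sexes was tested directly, though in males genotype cannot be told apart from handling of the pools. For Pabpc1 the female effect was lower than the male effect by 2.04 on the log2 scale (log2 -2.04, SE 0.26, adjusted p = 0.00018), with 138.5 ± 23.4 CPM in mutant females against 499.7 ± 56.0 CPM in mutant males (SD, n = 2 pools per group). The kinase Mast4 (-1.79, SE 0.31), the actin regulator Baiap2 (-2.14, SE 0.38), the Ral exchange factor Ralgds (-2.36, SE 0.39) and the splicing factor Snrnp70 (-1.56, SE 0.28) differed in the same direction, each at an adjusted p of 0.0153. Morn2 differed the other way (1.65, SE 0.34, 0.0467), with 91.65 ± 26.1 CPM in mutant females and 27.54 ± 1.63 CPM in mutant males. The other 4 of the 9 genes with a lower female effect were Slc2a1 (-3.12), mt-Atp8 (-1.75), Tmem243 (-2.14) and Tacc2 (-2.41), chosen after their values were seen. Baiap2 gave 0.31 in cells with at least 1500 genes, where mutant male replicate 2 had 12 somatotropes.

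Among gene lists, nuclear-encoded oxidative phosphorylation was called in the interaction: 63 of 71 genes had a higher effect in females, with 0 passing over all genes and 8 adjusted over the list alone (median 0.38, camera adjusted p = 1.43e-08; 0.0431 with an estimated correlation). Genes of 0.6 to 1 kb outside the list had a median of 0.43, and with the length trend removed the list had a median of 0.11 and 0 genes passing adjusted over the list alone (camera adjusted p = 0.0276; adjusted p = 0.546 with an estimated correlation). A difference between the sexes in this list is therefore not told apart from transcript length. Cholesterol synthesis had a lower effect in females (median -0.54, 4 of 22 adjusted over the list alone, camera adjusted p = 2.93e-05; adjusted p = 0.136 with an estimated correlation), as did glycolysis (-0.48, 0.000816; adjusted p = 0.553 with an estimated correlation). Also called were ribosomal proteins (0.28, 0.00716; adjusted p = 0.867 with an estimated correlation), heat shock genes (-0.56, 0.0288; adjusted p = 0.631) and erythroid markers (3.24, 0.0018; adjusted p = 0.553). Glucocorticoid response (-0.63, 0.0275; adjusted p = 0.804 with an estimated correlation), ion channels (-0.36, 0.0311; adjusted p = 0.771) and mitochondrially encoded transcripts (-0.27, 0.0364; adjusted p = 0.867) completed these calls. With the length trend removed, ribosomal proteins (adjusted p = 0.835) and ion channels (0.196) were not called, and the other lists were. Of 8247 genes, edgeR called 10 and DESeq2 called 1, with 841 and 272 at an unadjusted p under 0.05. Without the length trend edgeR called 7, and Morn2 was not among them. The count was 1 and 27 without control female replicates 1 and 2, 20 and 16 without control male replicates 1 and 2, 29 without mutant female replicate 1 and 5 without mutant male replicate 2.

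Female and male fold changes in somatotropes showed no correlation across 8247 genes (Spearman -0.009, Pearson 0.018). Most of these genes were called in neither sex, so this cannot exclude an effect shared by fewer genes. At an unadjusted p under 0.05, 148 genes were higher in females and 743 in males, with 30 shared where independent lists would share 13.3. Of 134 lower in females and 676 in males, 8 were shared against 11.0. The 217 genes that rose in males had median log2 values of 0.06 and 0.13 in the 2 mutant female pools relative to control females, and of 1.22 and 1.34 in the mutant male pools relative to control males.

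Control females and control males were compared for the baseline against which the genotype acts. Female somatotropes expressed Aebp1 at 122.1 ± 22.3 CPM against 0.868 ± 0.151 CPM in males (SD, n = 2 pools per group), and Pak7, a neuronal p21-activated kinase, at 31.05 ± 2.35 against 0.2437 CPM. Reln, the extracellular protein reelin, was at 38.75 ± 1.37 CPM in females and had 0 UMIs in control males, where the floor was 1.47 and 2.17 CPM. Calb1, a calcium buffer, was 4.15-fold higher in females (log2 2.05, SE 0.23, adjusted p = 2.14e-06) and Neb 6.14-fold (2.62, SE 0.31, 7.7e-06). Male somatotropes had more Gria4, an AMPA receptor subunit (5.24-fold, log2 -2.39, SE 0.33, 8.9e-05), and Myoc (2.99-fold, -1.58, SE 0.23, 0.000201). The Y-linked Ddx3y (93.14 ± 2.83 CPM), Eif2s3y (46.0 ± 9.22) and Uty (31.96 ± 1.09) had 0 UMIs in females, and Xist (1665 ± 596 CPM in females) had 0 in control male somatotropes. Aebp1, Reln and Calb1 are also high in female lactotropes. Taking all Prl in control female somatotropes as free RNA, this would bring at most 7.24 and 14.7 CPM of Aebp1, 5.11 and 12.4 CPM of Reln and 11.5 and 30.8 CPM of Calb1 to the 2 pools, below the levels found.

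Estrogen-responsive genes were among those higher in control females: Greb1 (1.44, SE 0.21) and Gal, which encodes galanin (4.97, SE 0.54), 2 of 9 sex steroid genes and also 2 adjusted over the list alone (median -0.02, mean 0.73, camera adjusted p = 0.000425 upward; adjusted p = 0.344 with an estimated correlation). Interferon response genes were lower in females, 2 of 16 and 3 adjusted over the list alone, with Iigp1 (-2.75, SE 0.41) and B2m (-1.54, SE 0.25) leading (median -0.79, camera adjusted p = 1.23e-07; adjusted p = 0.344 with an estimated correlation). Heat shock genes were lower, 2 of 15 and 5 adjusted over the list alone (Hsp90aa1, -0.70; Dnaja1, -0.76; camera adjusted p = 9.66e-06; adjusted p = 0.324 with an estimated correlation). Immediate early genes had 1 positive value of 25 and 0 called either way (camera adjusted p = 9.66e-06; adjusted p = 0.556 with an estimated correlation), and clock genes included 1 of 17 that was lower and 2 adjusted over the list alone (Nfil3, -1.32; camera adjusted p = 0.000425; adjusted p = 0.344 with an estimated correlation). Oxidative phosphorylation was called upward (0.0112; adjusted p = 0.324 with an estimated correlation, and 0.235 with the length trend removed) and erythroid markers downward (0.00356; adjusted p = 0.425), with 0 genes passing in either. EdgeR called 36 genes higher and 24 lower in females, and DESeq2 called 34, with 28 shared. The count was 98 and 102 without mutant female replicates 1 and 2, and 42 (25 higher) with genes of at least 5 times the level in another class left out, Aebp1 and Calb1 among them.

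The other cell classes, which are named by products other than growth hormone, were compared to see whether changes stayed within somatotropes. In males they did not. Endothelial cells of mutant males had 11.6 times as much Usp18, an interferon-induced protease (log2 3.53, SE 0.29, adjusted p = 8.33e-08; 278.0 ± 8.17 against 23.8 ± 5.46 CPM, SD, n = 2 pools per group), and more Fosl2 (2.55, SE 0.23) and Tiparp (2.90, SE 0.27), with less Tmem165 (-2.34), G0s2 (-1.90) and Mrpl34 (-2.09). Stem cells had more Upp1 (3.23), Arc (1.97) and Amd1 (1.78) and less Tmem53 (-1.70), G0s2 (-1.83) and Il17rd (-1.19). Lactotropes, the prolactin cells, had more of the actin-severing protein Dstn (1.61), Baiap2 (1.98) and Slc2a1 (2.10), and less Tmem238 (2.01-fold lower), Ebpl (-0.77) and Rdh14 (-1.03).

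Smaller classes in males changed too. Gonadotropes had more of the hexokinase Hk2 (3.32, SE 0.39), Slc2a1 (2.66, SE 0.31) and Pdcd4 (1.32, SE 0.19), and less Rasl11a (-2.25). Thyrotropes were not separated from this class: no cluster took their name. The larger gonadotrope cluster had Tshb among its 10 leading genes, with a score of 5.92 for gonadotropes and 4.14 for thyrotropes. Melanotropes had more Dstn (1.86), mt-Atp8 (2.07) and Btg1 (1.68), and less Socs3 (-2.13), Egr1 (-1.35) and Nfkbiz (-1.80). Macrophages had more of the chemokine Ccl5 (2.70), mt-Atp8 (2.25) and Hmox1, a heme-degrading enzyme (1.97), and less Stk17b (-1.74), the 1 lower gene. Btg1, Nmt1, Rpl38 and mt-Atp8 rose in all 7 classes tested, chosen after their values were seen, and Slc2a1 in all 6 classes in which it was tested (log2 1.62 to 3.24).

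The genes called in male somatotropes recurred across classes. The share with the same sign was 99.3% in lactotropes, 97.0% in stem cells, 91.7% in melanotropes, 90.9% in endothelial cells, 90.6% in gonadotropes and 81.8% in macrophages. In lactotropes 146 were called in the same direction where independent lists would share 7.3, and in stem cells 165 against 20.8. In females the same genes had the male sign in 50.9% to 71.4%. Of 143 such genes measured in all 7 classes, 108 (75.5%) had the same sign in all of them in males.

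**Figure D2:**
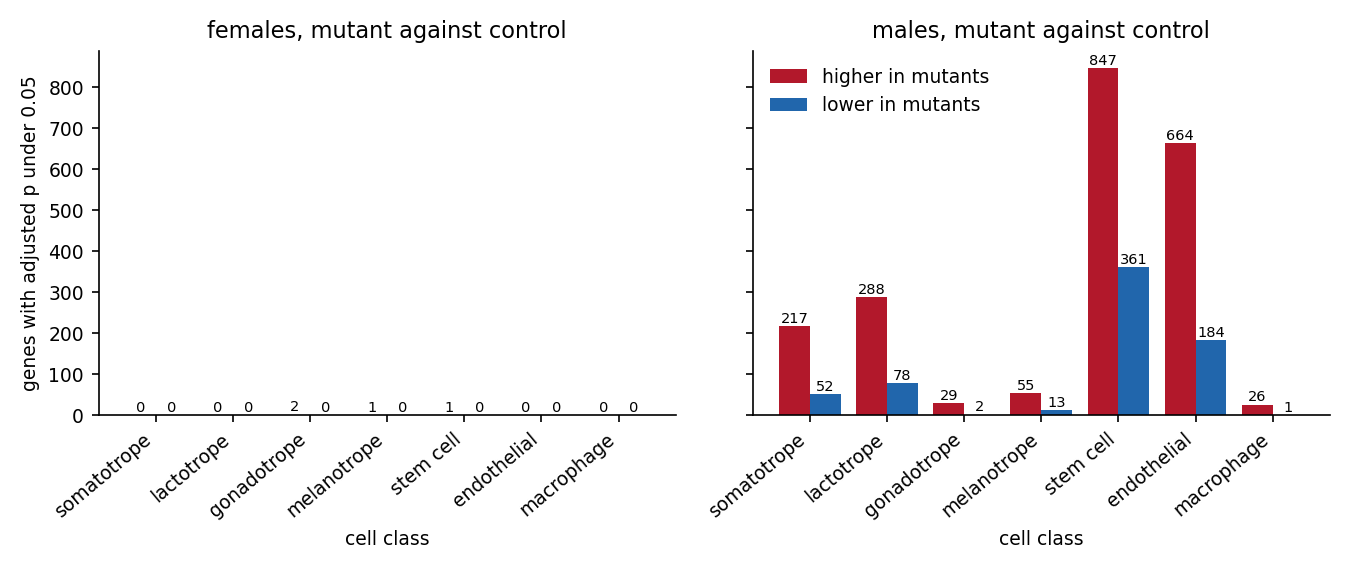
Number of genes with an adjusted p under 0.05 per cell class, in females and males, as bars from 0, red for higher and blue for lower in mutants. Male bars reach 847 higher and 361 lower in stem cells, and the female bars reach 2 at most.

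Interferon response genes in the endothelium had 10 of 25 that rose, 0 that fell and 15 that rose adjusted over the list alone (median 1.23; Usp18, Gbp2 2.23, Rtp4 1.99, Ifih1 1.87; camera adjusted p = 5.37e-15; adjusted p = 0.316 with an estimated correlation). In stem cells, 11 of 29 secretory granule genes rose, 13 adjusted over the list alone (Scg2 2.02, Rab27a 1.78, Pcsk1 1.54, Syt7 1.06). Camera gave an adjusted p of 9.6e-10, and of 0.346 with an estimated correlation. Scg2 was also a leading gene of a gonadotrope cluster, and stem cell droplets held 23900 to 38400 CPM of Gh per library. This list was not tested in stem cells with free RNA genes left out, so free RNA is not excluded as a source. Heat shock genes rose in 7 of 15 in stem cells, 13 adjusted over the list alone (Bag3 1.79, Dnajb1 1.10; camera adjusted p = 2.77e-08; adjusted p = 0.346 with an estimated correlation), and in 2 of 15 in lactotropes, 2 adjusted over the list alone (Bag3 1.49, Hspa8 0.65; camera adjusted p = 1.2e-10; adjusted p = 0.531 with an estimated correlation). In melanotropes 4 of 14 cholesterol synthesis genes rose, 8 adjusted over the list alone (Msmo1 1.61, Idi1 1.46; camera adjusted p = 9.36e-06; adjusted p = 0.223 with an estimated correlation). Every camera call in these 6 classes was lost with an estimated correlation.

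In female mutants, 4 genes passed in the 6 other classes together. Neat1, a nuclear long noncoding RNA, rose in gonadotropes (2.09, SE 0.31, adjusted p = 0.00654), Cyr61 in melanotropes (4.08, SE 0.78, 0.046) and Arc in stem cells (1.29, SE 0.18, 0.0202; n = 2 pools per group throughout). The other gene was Prl in gonadotrope droplets (1.48, SE 0.22, 0.00654), which cannot be read as gonadotrope expression. Prl made up 18.39% to 29.11% of UMIs in the lowest barcodes of the female libraries, and free RNA, with all Gh in these droplets taken as free, could bring up to 55100 to 120000 CPM per pool, so it is not excluded as the source of the 13000 to 46100 CPM found. In gonadotropes, melanotropes and stem cells, DESeq2 called 2, 0 and 14 genes where edgeR called 2, 1 and 1. EdgeR called 0 in endothelial cells, lactotropes and macrophages, with 468, 734 and 177 at an unadjusted p under 0.05 and 2, 13 and 0 by DESeq2. Without mutant female replicate 2 the total was 199. Without control female replicates 1 and 2 it was 12 and 45, without control male replicates 1 and 2 it was 22 and 19, without mutant female replicate 1 it was 30, and without mutant male replicates 1 and 2 it was 7 and 10. Interferon response genes in female endothelium had positive values in 25 of 25 (median 0.82), with 0 called over all genes and 5 that rose adjusted over the list alone (camera adjusted p = 4.65e-18; adjusted p = 0.307 with an estimated correlation). The level of this list lay above control females by 1.26 in mutant female replicate 1 and by 0.53 in replicate 2. Rsad2 stood at 402 and 36.4 CPM in these pools against 61.9 and 16 CPM in controls.

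In the other classes of males, 1909 genes were higher and 639 lower, 2548 calls in all: 848 of 7701 tested in endothelial cells, 31 of 8648 in gonadotropes, 366 of 12250 in lactotropes, 27 of 4604 in macrophages, 68 of 5817 in melanotropes and 1208 of 11625 in stem cells. DESeq2 called 1188. The total was 1495 and 982 without control male replicates 1 and 2, and 907 and 1461 without mutant male replicates 1 and 2. The split by direction depended on scaling: TMM gave 74.9% higher and library totals gave 42.6%, with 41.4% in place of 78.3% in endothelial cells, 34.3% in place of 70.1% in stem cells and 93.3% in place of 80.9% in melanotropes. With library totals the median over all genes in males shifted to -0.28 in endothelial cells, -0.21 in stem cells, -0.15 in gonadotropes, -0.12 in macrophages and 0.13 in melanotropes, and in females to -0.2 in melanotropes, -0.17 in stem cells, -0.12 in endothelial cells and -0.11 in gonadotropes and macrophages.

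**Figure D3:**
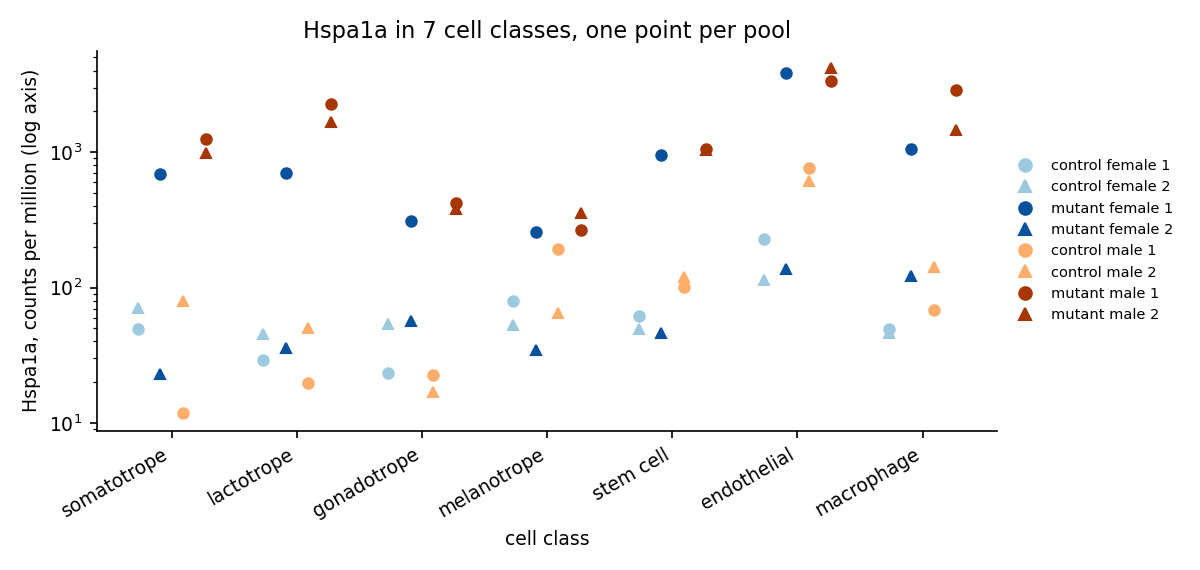
Hspa1a level in 7 cell classes, with 1 point per pool and CPM on a log axis. In somatotropes mutant male pools lay at 1250 and 986 CPM and mutant female replicate 1 at 687 CPM, with mutant female replicate 2 at 23.0 CPM.

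Hspa1a, the inducible HSP70, varied between mutant pools. In somatotropes it stood at 1250 and 986 CPM in mutant males against 11.8 and 80.2 CPM in control males (log2 4.65, SE 1.78, adjusted p = 0.305). In females it stood at 687 and 23.0 CPM in mutants against 49.6 and 70.3 CPM in controls (2.65, SE 1.70).

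Cells of some classes fell into different clusters by group in males. An endothelial cluster led by Cxcl10, Rsad2 and Iigp1 held 83 and 71 cells of the mutant male pools and 29 of mutant female replicate 1, with 1 cell from all the controls. A lactotrope cluster led by Hspa1b and Hspa1a held 68 and 94 cells of the mutant male pools and 2 of control male replicate 2. A stem cell cluster led by Thbs1, F3 and Krt8 held 59 and 62 cells of the mutant male pools, 33 of mutant female replicate 1 and 0 of the controls. Mutant female replicate 2 gave 0 of its 94 endothelial cells and 0 of its 94 stem cells to these clusters, so they did not hold cells of every mutant pool. Both mutant female pools gave 0 cells to that lactotrope cluster. Somatotropes fell into a high-UMI and a low-UMI cluster, the latter holding 41.5% and 67.0% of somatotropes in control males and 76.9% and 61.2% in mutant males. At a clustering resolution of 0.5, 22.1% and 37.3% of these somatotropes in control males and 46.3% and 44.9% in mutant males were named lactotropes. The median mitochondrial share of male somatotropes was 4.81% and 8.36% in controls and 11.1% and 7.18% in mutants. Male somatotrope calls were 216 at that resolution (175 shared) and 324 in the high-UMI cluster alone (174 shared).

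The share of somatotropes among kept barcodes did not pass a test in either sex. It was 11.2 ± 1.6% in mutant males and 15.1 ± 0.858% in control males (SD, n = 2 pools, -3.87 points, exact permutation p = 0.333, the smallest the design allows), and 5.41 ± 5.46% in mutant females against 8.51 ± 2.93% in control females (-3.11 points, exact permutation p = 0.667). The mutant female pools differed, with 9.26% in replicate 1 and 1.55% in replicate 2, where free RNA barcodes enlarge the denominator. Among named cells the female shares were 8.07 ± 2.48% and 9.06 ± 3.1%. As cell counts in edgeR, the log2 values were -0.68 in females (adjusted p = 0.726) and -0.43 in males (adjusted p = 0.989). Macrophages made up 7.1 ± 0.321% in mutant males and 4.03 ± 0.151% in control males (n = 2 pools, exact permutation p = 0.333). Lactotropes made up 25.6 ± 18.9% in mutant females and 44.7 ± 7.67% in control females (n = 2 pools, exact permutation p = 0.333), a share that the free RNA cluster of mutant female replicate 2 enters as its denominator. Among named cells alone the lactotrope shares were 45.6 ± 6.09% and 47.6 ± 8.26%. Barcodes left unnamed made up 40.6 ± 49.4% in mutant and 6.07 ± 0.194% in control females, and 5.56 ± 0.563% in mutant and 4.52 ± 1.7% in control males (n = 2 pools).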

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

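Chosen only after results were seen were the tests on signs across cell classes, on differences between pools, on the transcript length trend and on Hspa1a, while the settings without free RNA genes, with equal cells and without a library were planned but held against these explanations only afterwards.

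The contrast of mutants against controls in somatotropes differed between the sexes for 10 genes by edgeR's interaction test, and DESeq2 called 1. In males this contrast cannot tell genotype from handling of the pools, so a sex-specific effect of genotype is not shown. The difference, female effect minus male effect on the log2 scale, was 1.65 for Morn2, -2.04 for Pabpc1, -1.79 for Mast4, -2.14 for Baiap2, -2.36 for Ralgds and -1.56 for Snrnp70. These were picked out because their difference between females and males passed its own test. With the transcript length trend removed 7 genes passed, and Morn2 was not among them.

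A transcript outside the comparisons, P1_gp003, had 127 UMIs in the mutant libraries and 0 in the controls. It was picked out as a signal in data that no comparison used, above the level in controls. A UMI of it was found in 34 of 372 mutant somatotropes (9.14%, 95% interval 6.41 to 12.5%; median 5239.5 UMIs per cell) and in 0 of 761 control somatotropes. The share of somatotropes was 13.0% and 10.8% in mutant female replicates 1 and 2, and 10.2% and 3.06% in mutant male replicates 1 and 2. In mutant lactotropes the share was 1.72% at a median of 14770 UMIs, and in gonadotropes 2.84% at 14022. It was 1.69% in corticotropes, 1.5% in pituicytes and 1.46% in stem cells. In mutant endothelial cells it was 0 of 520 at a median of 2804, and none was found in lymphocytes, macrophages, melanotropes or stromal cells.

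Hemoglobin made up 3.539% of UMIs in the 2000 barcodes of fewest UMIs of mutant female replicate 2, against 0.165% to 0.627% in the other libraries. This was picked out as a signal in barcodes that no comparison used, above every control library.

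The genotype calls of males recurred across cell classes. At least 81.8% of the genes called in somatotropes had the same sign in each of the 6 other classes, which argues against loss of the receptor acting inside somatotropes alone. Free RNA of genes at least 5 times higher in another class is argued against as the source of most of these calls. With such genes left out there were 2600 male calls in the other classes, against 2548 with them. Genes of similar level in several classes stayed in this test, so it cannot exclude free RNA for them. With each library's trend with transcript length removed, male somatotropes gave 266 calls, against 269 with it. Recurrence across classes was not recomputed with the trend removed, so these counts cannot decide whether the trend contributes to it. The rank correlation of male fold changes with length was 0.17 in somatotropes. It was 0.1 in endothelial cells and lactotropes, 0.19 in melanotropes and 0.18 in stem cells, but -0.08 in gonadotropes and -0.14 in macrophages. A difference in handling between the pools cannot be told apart from genotype, because both would follow the groups: pools of the same male group differed in a way that recurred at a median rank correlation of 0.06, and pools of different genotype at 0.32. A change reaching all cells, such as altered circulating growth hormone in mutant males, stays open as untested.

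EdgeR called 0 genes in female somatotropes and 269 in males, with 282 and 1419 at an unadjusted p under 0.05, and 0 and 82 by DESeq2. Fewer cells in females are argued against as the whole cause, since males gave 90 calls with 74 somatotropes drawn from every library. That is below the 269 with all cells, so the number of cells does affect the count. Free RNA in mutant female replicate 2 is argued against as the whole cause by 14 female calls without it, below the 95 and 175 that males gave without a mutant library. In the other classes, female calls went from 4 to 199 without it, against 907 and 1461 in males without a mutant library. The 199 calls rest on mutant female replicate 1 as the only mutant female pool, itself high in Hspa1a (687 CPM in somatotropes), so whether replicate 2 masks a genotype effect stays open. A larger spread between female pools cannot be told apart from a smaller effect: the biological coefficient of variation was 0.183 in females and 0.146 in males, a ratio of 1.25. The interaction passed for 10 of 8247 genes, and for the other genes a difference between the sexes stays open.

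Among heat shock transcripts, Hspa1a was high in 3 of the 4 mutant libraries. Hspa1a stood at 687, 1250 and 986 CPM in somatotropes of mutant female replicate 1 and mutant male replicates 1 and 2, and at 23 CPM in mutant female replicate 2, below the 49.6 and 70.3 CPM of control females. In somatotropes Hspa1a was thus not raised in every mutant pool. That single library cannot decide whether loss of the receptor raises it. Stress during the handling of those 3 pools is a candidate explanation: Hspa1a lay above both controls of the same sex in all 3 in 7 of 7 cell classes, as this would need. A genotype effect on stress in the animal would give the same picture in those 3 pools, and was not tested. These explanations were weighed for Hspa1a only. Of the same list, Hspa8 and Dnajb4 lay above all controls in all 4 mutant pools. The level of the list also lay above control females in mutant female replicate 2, though by less than in replicate 1.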

How the results depend on the processing

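Tests with cells of at least 1500 genes, the high-UMI somatotrope cluster alone, the length trend removed, DESeq2 size factors in list tests and shares of named cells were chosen after the results were seen. All other alternatives were planned. Of the values of named genes past the threshold under the alternatives, 1571 kept their direction and their side of the threshold, 187 kept their direction but not the threshold, and 2 reversed. For lists called by camera these numbers were 137, 29 and 2. Unless fewer libraries, cells or genes entered the test by construction, the cause was not tested. Leaving out a library leaves its group with 1 library, which is assumed to vary like the other groups.

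With the DESeq2 Wald test the calls were 82 in male somatotropes, 22 over both sexes, 1 for the interaction, 34 for control sex, 31 in other classes of females and 1188 in other classes of males. Without a filter on low counts they were 4 in female and 417 in male somatotropes, 98 over both sexes, 74 for the interaction, 195 for control sex, and 233 and 3917 in other classes of females and males. With at least 200 genes per barcode they were 472 in males, 107 over both sexes, 25 for the interaction and 216 for control sex. With equal numbers of cells they were 90, 27, 5 and 20 in the same order, and 1681 in other classes of males. With all kept cells summed they were 1025, 457, 63 and 1528.

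Library totals gave 17 calls for the interaction and 2 in other classes of females. Leaving out free RNA genes gave 16 for the interaction. In other classes of females, only the 4 libraries compared gave 31, at most 10% mitochondrial UMIs gave 2 and no removal by Scrublet score gave 2; the latter gave 1475 in other classes of males. Cells with at least 1500 genes, of which mutant male replicates 1 and 2 held 23 and 12 somatotropes, the latter below the minimum of 20 set for other classes, gave 1 call in female and 82 in male somatotropes and 23 over both sexes.

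Leaving out 1 library at a time gave 0 to 14 calls in female somatotropes, 95 to 342 in males (342 without mutant female replicate 2), 16 to 77 over both sexes, 1 to 29 for the interaction and 40 to 102 for control sex. In other classes it gave 7 to 199 in females and 907 to 3155 in males (3155 without mutant female replicate 1).

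Of lists in somatotropes, 4 were called in females and 6 in males. An estimated correlation gave 0 in each sex, fry gave 0 in females and the high-UMI cluster gave 2 in females, while cells with at least 1500 genes gave 10 in males. With the length trend removed 3 were called in females and 5 in males, and nuclear-encoded oxidative phosphorylation was lost in both (adjusted p = 0.341 and 0.133). Leaving out 1 library gave 4 to 8 in females and 5 to 7 in males. The correlation of female and male fold changes was 0.04 in the high-UMI cluster and -0.077 to 0.079 with 1 library left out. Shares of somatotropes kept their direction under the other filters, the lower resolution, the other denominators and cell counts in edgeR. The size of the class depended on the filter. With at least 200 genes per barcode, 1766 and 850 barcodes of control female replicates 1 and 2 were named somatotropes, against 205 and 82 in the main setting. Shares were not tested with a library left out; mutant female replicate 1 alone, at 9.26%, lies above the control female mean of 8.51%.

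These lists turned in females, given as adjusted p: hormones of other endocrine cells upward without control female replicate 1 (0.00269); gonadotrope markers downward (0.00104) and mitochondrially encoded transcripts downward (0.0488) without control female replicate 2; glucocorticoid response upward without mutant female replicate 1 (0.0422); erythroid markers downward (0.314) and immediate early genes downward (2.82e-38) without mutant female replicate 2. Over all libraries left out singly, adjusted p ran from 0.00269 to 0.992 for hormones of other endocrine cells, from 4.07e-05 to 0.997 for gonadotrope markers in somatotropes, females; from 0.000745 to 0.819 for mitochondrially encoded transcripts in somatotropes, females; from 0.00212 to 0.992 for glucocorticoid response, from 3.77e-28 to 0.314 for erythroid markers in somatotropes, females, and from 2.82e-38 to 0.992 for immediate early genes. In males, cells with at least 1500 genes turned glucocorticoid response (0.153), hormones of other endocrine cells (0.0141), interferon response (0.0194) and JAK-STAT signalling (0.00398) downward. They also turned Baiap2 in males to -0.38 and in the interaction to 0.31. With all kept cells summed, Msi1 over both sexes was 0.48 and Prl between control sexes was 3.14, in a mix of all classes.

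Replicate numbers do not pair the libraries as far as the data show. The deviations of replicate 1 from replicate 2 correlated at -0.09 between control and mutant females and at -0.053 between control and mutant males, so samples only share a number. With the replicate number as a block, calls were 2 in female and 263 in male somatotropes, 43 over both sexes, 9 for the interaction, 62 for control sex, and 11 and 2748 in other classes of females and males; lists were 4 and 6, and the correlation of fold changes was -0.008.

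Depth limits genes of low level: in simulated data 24% of 2-fold changes were recovered in female somatotropes and 42% in males. The simulation gave both sexes the same spread. In the data the biological coefficient of variation was 0.183 in females and 0.146 in males, so recovery in females may be overstated. Neighbouring choices of variable genes, components and neighbours were not tried.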

Other observations

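Of the tests in this part, the comparison with other splits of the libraries was chosen after the result was seen.

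Endothelial cells of mutant males had more transcripts of several genes of signalling feedback and metabolism. Nfil3, a transcription factor of the clock list (3.30, SE 0.34), Slc2a1 (3.24, SE 0.33), Errfi1, an inhibitor of EGF receptor signalling (2.41, SE 0.23), Ddit4 (2.33, SE 0.28) and the MAPK feedback gene Spry4 (1.93, SE 0.27) rose. Of 13 glucocorticoid response genes 5 rose and 0 fell, also adjusted over the list alone (median 1.73, camera adjusted p = 3.92e-08; adjusted p = 0.316 with an estimated correlation). Of 20 MAPK feedback genes 7 rose and 0 fell, and 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000696; adjusted p = 0.316 with an estimated correlation). Of 27 leptin receptor and JAK-STAT genes 8 rose and 0 fell, 12 rose adjusted over the list alone, among them Bcl3 (2.24), Stat3 (1.38) and Jak2 (2.61) (camera adjusted p = 0.000163; adjusted p = 0.421 with an estimated correlation). Cxcl10, an interferon-induced chemokine, was at 3620 and 3820 CPM in endothelium of the mutant male pools and at 715 and 251 CPM in control males.

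Immediate early genes were among those that fell in melanotropes of mutant males. Egr1 (-1.35, SE 0.25), Egr2 (-4.84, SE 1.03) and Btg2 (-1.59, SE 0.32) fell and Btg1 (1.68, SE 0.24) rose, 4 of 26 falling and 1 rising, with 5 and 3 adjusted over the list alone (median -0.44, camera adjusted p = 0.00132; adjusted p = 0.533 with an estimated correlation). In stem cells of mutant males, Atf4 (1.36, SE 0.19), Hspa5 (1.00, SE 0.2) and Xbp1 (0.85, SE 0.19) were among 7 of 26 unfolded protein response genes that rose, with 0 falling and 8 rising adjusted over the list alone (camera adjusted p = 0.00149; adjusted p = 0.467 with an estimated correlation).

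With sex as a term in the model, mutant against control gave 25 calls in somatotropes over all 8 libraries. Of 34 splits of the libraries into groups of 4 that could be fitted, 3 gave as many, the real one included, and the highest other gave 71. The splits with 35 and 71 calls joined both mutant male pools with control female replicate 1 and 1 mutant female pool. Both splits thus still set mutant males against control males, so they cannot decide whether chance gave the 25 calls. The remaining splits that could be fitted gave 0 to 3 calls.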
